A study of Mus musculus with 6 samples.

How the data were processed

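RNA-seq libraries of cells sorted from uterine epithelial isolates were measured, 3 per fraction, from the same 3 mice. Per the labels' protocols, mice with an Axin2rtTA and a tetO-H2B-GFP transgene were ovariectomized at 4 weeks of age, rested for 2 weeks and given doxycycline, and uteri were collected 4 days later, at 6 weeks of age. Endometrial epithelial cells were isolated and sorted by GFP, and RNA was depleted of ribosomal RNA with Ribo-Zero Gold, per the labels' protocols. The labels number the libraries by mouse, and they also speak of pooling cells of the mice. Each library was treated as 1 fraction of 1 mouse, and if the libraries came from a pool, the p-values measure the spread between libraries of that pool.

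The authors deposited whole-number read counts per gene for each library, which sum to between 49714402 and 59597315 per library. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.3a, featureCounts 1.5.3 of the Subread package, StringTie 1.3.3, edgeR 3.22.5 and the mm10 build. The annotation version and whether counting used strand are not given in the sources used here. A mapping summary by the authors gives, per the file headers, read numbers and the percentage of read pairs assigned to a feature, which was 29.26 to 38.86 percent for pairs assigned to 1 feature. The authors' deposited comparison table gives, per the file headers, log2 fold changes and log2 CPM, a test statistic treated here as a score, and p-values and FDR values per gene, and its counts equal those of the count table. Of 18 thresholds tried, 1 gave exactly its 15469 genes: above 0.5 CPM in at least 3 libraries. This filter was inferred from the genes in the table, and the fit used here with that filter gave log2 fold changes that differ from the deposited ones by at most 4.62e-14.

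Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, libraries were scaled with TMM factors (group means 0.944 for the libraries labelled Axin2- and 1.06 for those labelled Axin2+), and each gene was tested with the robust quasi-likelihood F test between fractions. P-values were adjusted by Benjamini-Hochberg over 16896 genes, with a threshold of 0.05. The standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. Ribosomal RNA genes took 18.2 ± 4.85 and 15.96 ± 1.06 percent of the counts (SD, n = 3 each) in the libraries labelled Axin2- and Axin2+. Within a fraction the libraries correlated across genes with r of at least 0.960, and between fractions with at most 0.926; genes are not independent replicates. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom within a fraction was 63.5. The pairing by mouse comes from the labels. Deviations from the fraction means correlated across genes between the libraries of mice 1, 2 and 3 at 0.36, 0.02 and -0.19. Libraries of different mice reached 0.38, for that labelled Axin2- of mouse 2 and that labelled Axin2+ of mouse 3.

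Before the data were examined, 32 gene lists, the tests and the rule for named genes were fixed. The rule names Axin2, Lgr5, Foxa2, Esr1, Pgr and Epcam. It adds in each direction the 12 genes with the largest fold among those that passed, had a mean of at least 5 CPM and moved the same way in all 3 mice, leaving out predicted genes, and the 3 genes with the smallest p. From each list it takes up to 4 members with the smallest p, or 2 with the highest CPM where none passed. It gave 142 genes, some of which are described. Genes outside the rule that are named because 5 or fewer members of a list moved in a direction were chosen after their values were seen. Of 783 listed genes 743 were found under the listed symbol, 15 under an older one and 25 not at all. Lists with at least 3 tested members, 31 in all, were tested with camera at a preset correlation of 0.01, which called 18. With an estimated correlation camera called 0, while 8 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way on balance, called 19.

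Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of 138 named genes with coordinates 57 overlapped another annotated gene, 15 of them a protein-coding one, and without a stated strand setting their reads cannot be told from those of the partner with certainty. Among those with a protein-coding partner are Lgr5, Gpx2, Ccnd1 and Muc4. A gene at 0 in a whole fraction was given a bound from a floor of 3 counts per library. A gene with 1 to 3 reads in a fraction was given a ratio with an exact 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

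The fit was tested on simulated counts of 16587 genes for this comparison. It recovered 4.84% of the genes changed 1.5-fold, 28.8% of those changed 2-fold and 70.8% of those changed 4-fold, with 4 false among 77 calls. Only 62, 66 and 72 genes were changed at these folds, far fewer than the 4618 called in the data. With so few changes the adjusted threshold is stricter, so these shares do not give the recovery in the data. The list test called the 1 list that was shifted and 0 others. Simulated genes were drawn independently of each other, so the list test was not tried on correlated genes. In the data the estimated correlation within a list reached 0.90, for the cytosolic ribosomal protein genes. Alternatives were the mouse as a block, RLE, upper quartile and library-size scaling, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a test against a fold of 1.5, an estimated correlation, fry, and leaving out each library or mouse. A fit without ribosomal and abundant structural RNA genes, and one with the inferred filter of the authors' table, were added after seeing the data.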

Results

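Ribosomal RNA-depleted total RNA was sequenced from cells sorted from uterine epithelial isolates of 3 ovariectomized mice. In these mice the Axin2 promoter drives the rtTA activator, which with doxycycline switches on a histone H2B-GFP fusion. Cells with Axin2 promoter activity thus become fluorescent. Each mouse gave a fluorescent fraction, labelled Axin2+, and a non-fluorescent fraction, labelled Axin2-, which made 6 libraries, 3 per fraction. Gene counts summed to between 49714402 and 59597315 per library, and 16896 of the 26586 genes in the table had enough counts to be tested. The comparison asks which transcripts distinguish the fluorescent from the non-fluorescent fraction.

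Axin2, whose promoter drives the reporter, was measured first as a check on the labels. Its transcript (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783 on the plus strand of mm10) stood at 369, 357 and 356 CPM (counts scaled by library size and TMM factor) in the libraries labelled Axin2- of mice 1, 2 and 3. In the libraries labelled Axin2+ it stood at 165, 243 and 299 CPM. The means were 361 ± 6.85 and 236 ± 67.7 CPM (SD, n = 3 each), and the level was lower in the library labelled Axin2+ in 3 of 3 mice. The log2 fold change of -0.61 ± 0.21 (SE) did not pass the edgeR test (adjusted p = 0.0710). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow when the pairing by mouse is ignored. Over 19 other settings the log2 fold change ranged from -0.82 to -0.37 and the adjusted p from 0.0260 to 0.241. It passed in DESeq2 (adjusted p = 0.0260) and in edgeR without the library labelled Axin2+ of mouse 3 (log2 fold change -0.82, adjusted p = 0.0290). The Axin2 transcript thus did not bear out the labels, but its difference did not pass the main test and cannot show that they are wrong. Every direction given for a gene is that of the libraries as they are labelled.

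Epithelial transcripts were far higher, and smooth muscle and stromal transcripts far lower, in the libraries labelled Axin2+ than in those labelled Axin2-. Epcam, an adhesion molecule of epithelial cells, rose from 12.4 ± 5.45 to 227 ± 25.03 CPM (SD, n = 3 libraries each, as in all values of this form), a log2 fold change of 4.19 ± 0.34 (SE) with an edgeR adjusted p of 0.000419. Lgr5, a receptor for R-spondins and a Wnt target, rose from 4.84 ± 2.52 to 67.5 ± 13.4 CPM. Foxa2, a transcription factor of uterine glands, rose from 0.185 ± 0.142 to 23.2 ± 2.67 CPM. Myh11, the smooth muscle myosin heavy chain, fell from 2030.2 ± 1075 to 35.04 ± 3.45 CPM. Both fractions came from epithelial isolates per the labels. In the libraries labelled Axin2- smooth muscle and stromal transcripts were nonetheless plentiful, with Acta2 at 707 ± 294 and Col5a1 at 766 ± 338 CPM. Those labelled Axin2+ held macrophage transcripts, with Lyz2 at 962 ± 648 and Csf1r at 314 ± 257 CPM. The comparison is thus not one of epithelium against epithelium. CPM are not scaled by gene length, so levels of different genes do not give shares of cells. Esr1, the estrogen receptor, stood at 765 ± 328 CPM in the libraries labelled Axin2- and 591 ± 130.1 CPM in those labelled Axin2+, and did not pass (log2 fold change -0.37 ± 0.32 SE, edgeR adjusted p = 0.420). Its log2 fold change was 0.030 without the library labelled Axin2- of mouse 2. Pgr, the progesterone receptor, stood at 226 ± 88.5 and 343 ± 75.6 CPM and did not pass either (edgeR adjusted p = 0.164). Pgr passed with the mouse as a block (adjusted p = 0.0325) and without the library labelled Axin2- of mouse 2 (log2 fold change 0.97, adjusted p = 0.0207).

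**Figure D1:**
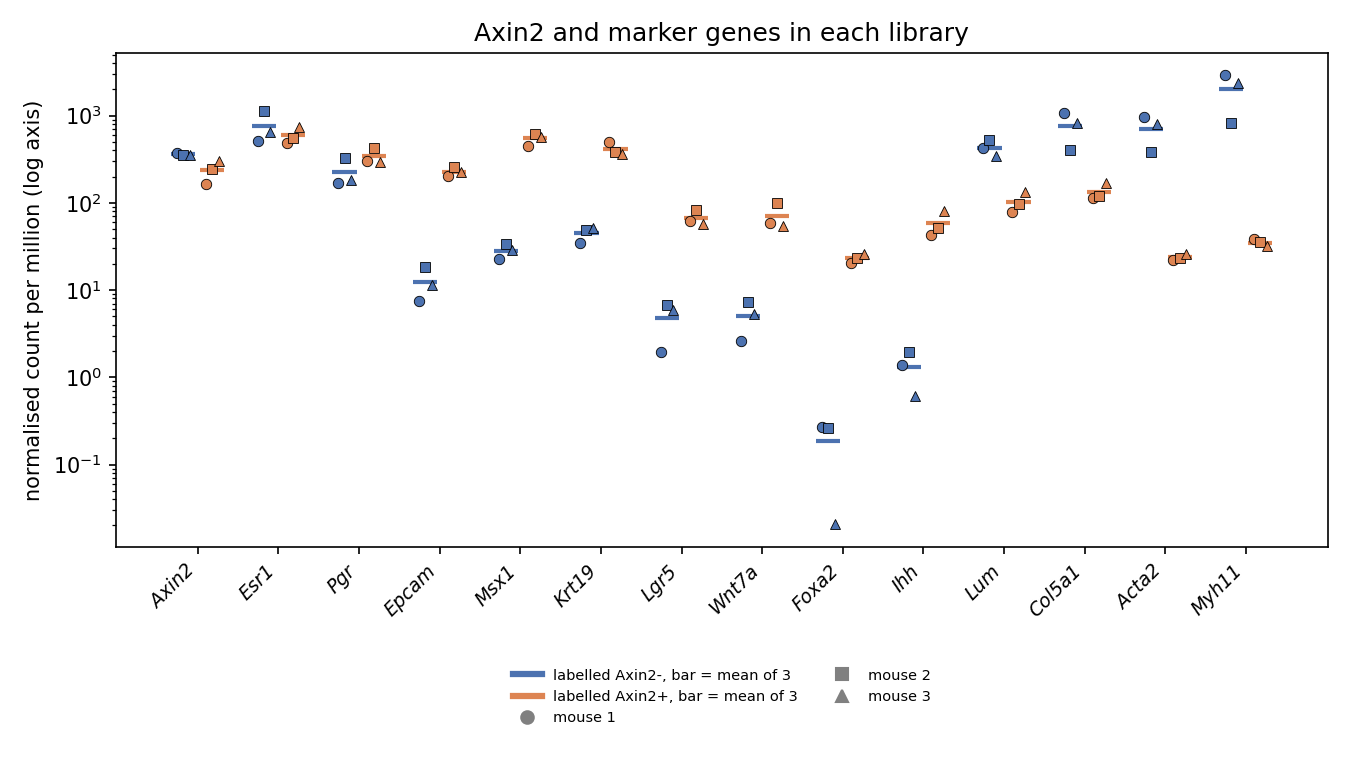
Normalised CPM on a log axis for 14 genes in each of the 6 libraries, grouped by label; marker shapes stand for the mouse and bars for the mean of 3 libraries. Epcam lies between 7.58 and 18.3 CPM in the libraries labelled Axin2- and between 205 and 254 CPM in those labelled Axin2+, and Myh11 between 822 and 2882 CPM and between 31.6 and 38.5 CPM.

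Genes common to epithelia rose together in the libraries labelled Axin2+, and so did most genes of the uterine glands and of the luminal epithelium. Of the general epithelial genes 24 of 24 rose (24 adjusted over the list alone), with a median log2 fold change of 3.69. Camera, which compares a list with all other genes, gave it an adjusted p of 7.16e-45, and adjusted p = 0.102 with an estimated correlation. The homeobox gene Msx1 rose from 28.4 ± 5.58 to 546 ± 87.4 CPM, the keratin Krt19 rose from 44.97 ± 8.89 to 416 ± 68.2 CPM and the protease inhibitor Spint2 rose from 36.8 ± 4.999 to 237 ± 19.2 CPM. Of the uterine gland genes 7 of 10 rose and 1, Gpx3, fell (7 and 1 adjusted over the list alone), with a median of 4.39. Its camera adjusted p was 7.17e-09, with adjusted p = 0.102 with an estimated correlation. Cxcl15, a chemokine of gland epithelium, had 2 reads in the 3 libraries labelled Axin2- together and 2456 in those labelled Axin2+, a ratio of 1172 with a 95% counting interval of 324 to 9687. Prom1, which encodes prominin 1, rose by 4.73 ± 0.33 (SE) on the log2 scale, and the retinaldehyde dehydrogenase Aldh1a1 rose from 14.7 ± 4.92 to 153 ± 34.1 CPM. Of the luminal epithelium genes 9 of 13 rose (9 rose and 1 fell adjusted over the list alone), with a median of 2.94. Its camera adjusted p was 2.21e-07, with adjusted p = 0.102 with an estimated correlation. Wnt7a, a Wnt ligand of the luminal epithelium, rose from 5.04 ± 2.34 to 71.3 ± 24.7 CPM, and the growth factor receptor Met rose from 7.80 ± 1.01 to 64.98 ± 7.06 CPM. The smooth muscle and stromal lists moved the other way in the same libraries, with medians of -2.89 and -1.87.

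Genes of ciliated cells had no common direction. Of 15 tested, 2 rose, Foxj1 and Tekt4, and 2 fell, Ccno and Rfx2 (2 and 2 adjusted over the list alone; camera adjusted p = 0.624). The list had a median of -0.46 and a mean of 0.19, which differ in sign, and its median was 0.13 without the library labelled Axin2- of mouse 1. Foxj1, the regulator of motile cilia, rose from 0.989 ± 0.406 to 4.30 ± 1.48 CPM, and did not pass without that library (edgeR adjusted p = 0.0519). Tekt4 had 3 reads against 98, a ratio of 31.2 with a 95% counting interval of 10.4 to 154, and did not pass without the library labelled Axin2- of mouse 2 (adjusted p = 0.0549). Its fitted log2 fold change, 4.80, was 5.70 without the library labelled Axin2- of mouse 1. Ccno did not pass without the library labelled Axin2- of mouse 3 (0.0520) or that labelled Axin2+ of mouse 2 (0.0561). Rfx2 did not pass without the library labelled Axin2- of mouse 1 (0.0563) or those labelled Axin2+ of mice 2 and 3 (0.0732 and 0.0532). With library-size scaling Rfx2 did not pass either (0.0593). With the library labelled Axin2- of mouse 1 left out, 2 members passed.

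**Figure D2:**
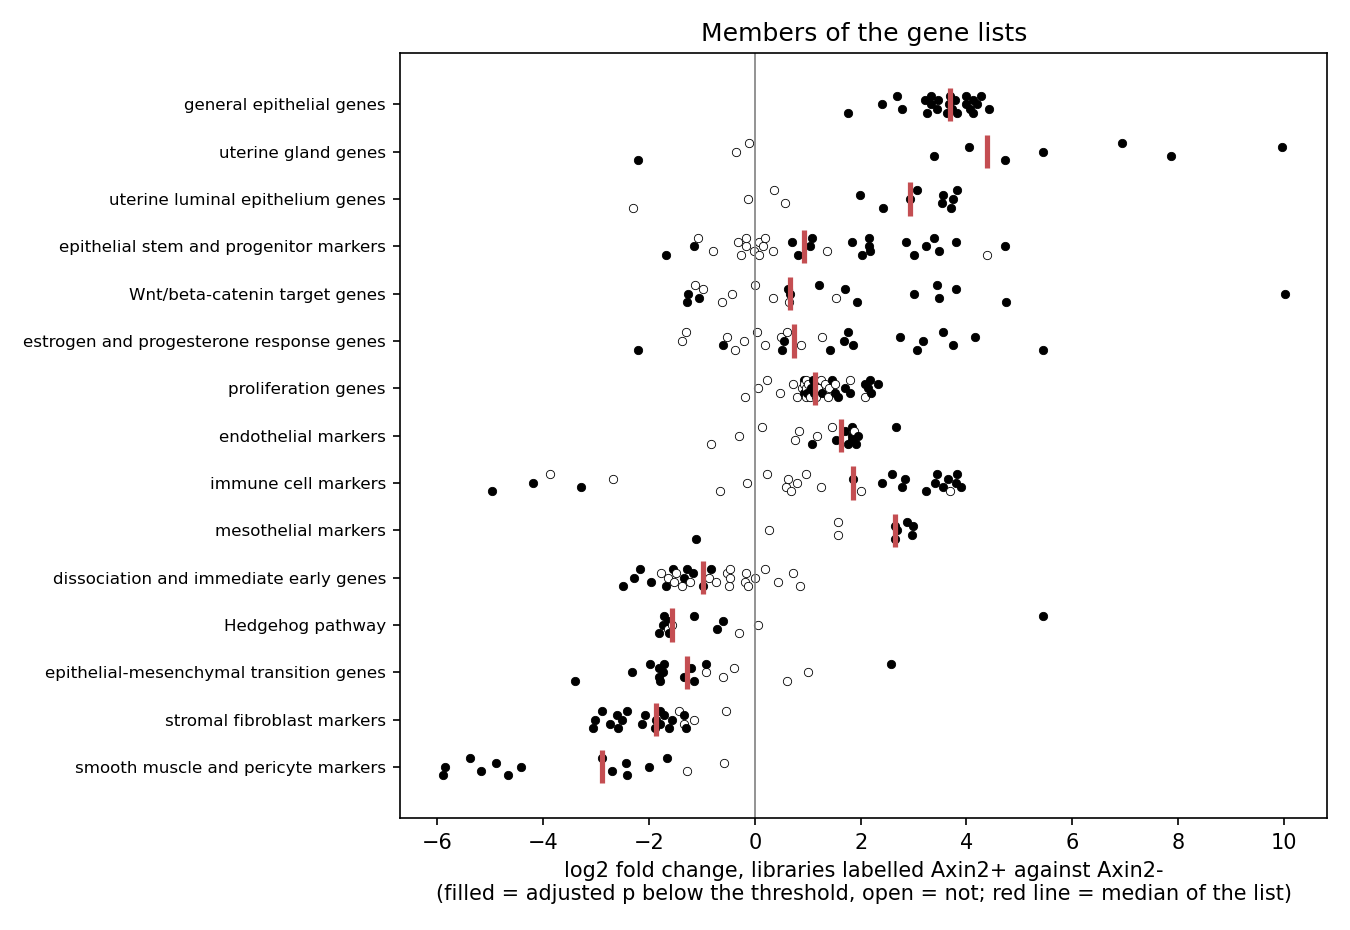
Log2 fold change of each tested member of 15 gene lists, libraries labelled Axin2+ over those labelled Axin2-; filled points passed the edgeR test, open points did not, and the red line is the median of the list. The general epithelial genes lie to the right of 0 around a median of 3.69, and the smooth muscle and pericyte markers to the left around -2.89.

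Most targets of Wnt/beta-catenin signalling that changed were higher in the libraries labelled Axin2+, whereas Axin2 itself, also a target, was lower there without passing the test. Of 22 tested, 11 rose and 3 fell (12 and 5 adjusted over the list alone), with a median of 0.66. The camera adjusted p was 0.000361, with adjusted p = 0.158 with an estimated correlation. Cell type lists moved further in the same libraries, with medians of 3.69 for the general epithelial genes, -1.87 for the stromal fibroblast markers and -2.89 for the smooth muscle and pericyte markers. Lgr5 rose by 3.80 ± 0.46 (SE) on the log2 scale, Ccnd1, which encodes cyclin D1, rose from 14.8 ± 2.72 to 162 ± 16.8 CPM, and Rnf43, a ubiquitin ligase that removes Wnt receptors, rose from 9.79 ± 2.62 to 109 ± 10.2 CPM. Wif1, a secreted Wnt inhibitor, had 1 read in the libraries labelled Axin2- against 1471, a ratio of 1404 with a 95% counting interval of 252 to 55511. That read came from mouse 2, and without its library Wif1 was at 0 there, at least 150.3-fold below the libraries labelled Axin2+. The fitted log2 fold change of Wif1, 10.03, was 9.29 without the library labelled Axin2+ of mouse 3. The members that fell were Nkd1, Nkd2 and Myc, with log2 fold changes of -1.27, -1.06 and -1.28. Of the Wnt ligands, receptors and modulators 9 of 42 rose and 15 fell (12 and 21 adjusted over the list alone; camera adjusted p = 0.153). The receptor Fzd6 rose from 17.9 ± 2.56 to 117 ± 18.7 CPM, whereas the receptor Fzd7 fell from 133 ± 13.6 to 44.3 ± 1.66 CPM. The secreted Wnt antagonist Sfrp4 fell from 142 ± 52.7 to 11.3 ± 3.50 CPM, and the R-spondin Rspo3 fell from 103 ± 38.8 to 9.90 ± 1.69 CPM. Of the epithelial stem and progenitor markers 16 of 32 rose and 2, Klf4 and Cdh2, fell (16 and 2 adjusted over the list alone), with a median of 0.93. Its camera adjusted p was 7.31e-06, with adjusted p = 0.153 with an estimated correlation. The integrin Itga6 rose from 26.8 ± 2.22 to 108 ± 18.4 CPM and Cd24a, a surface glycoprotein, rose from 29.7 ± 9.53 to 330.3 ± 100.2 CPM. Leaving out the library labelled Axin2- of mouse 1 left 13 Wnt ligands, receptors and modulators that passed.

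Of the estrogen and progesterone response genes 13 of 26 rose and 2, Ncoa1 and Gpx3, fell (14 and 3 adjusted over the list alone), with a median of 0.74. The camera adjusted p was 0.000670, with adjusted p = 0.216 with an estimated correlation. Ihh, the hedgehog ligand of the uterine epithelium, rose from 1.32 ± 0.673 to 58.3 ± 19.7 CPM, the mucin Muc1 rose by 1.76 ± 0.23 (SE) on the log2 scale, and Lifr, a receptor for leukemia inhibitory factor, rose from 65.9 ± 9.40 to 211 ± 38.6 CPM. Of the Hedgehog pathway 8 of 13 members fell, Ihh was the 1 that rose, and 4 did not pass (8 and 1 adjusted over the list alone). Its median of -1.57 was -0.93 without the library labelled Axin2- of mouse 1 (camera adjusted p = 0.00547 with all libraries, and adjusted p = 0.443 with an estimated correlation). The receptor Ptch1 fell from 670.1 ± 213 to 217 ± 52.7 CPM and the transcription factor Gli2 fell from 127 ± 16.5 to 36.1 ± 15.4 CPM. The stromal fibroblast markers fell alongside, 19 of 23 with a median of -1.87, and the general epithelial genes rose with Ihh. Of the proliferation genes 18 of 40 rose (28 adjusted over the list alone), with a median of 1.15. The camera adjusted p was 2.21e-07, with adjusted p = 0.443 with an estimated correlation. The replication helicase subunits Mcm2 and Mcm6 rose from 23.3 ± 1.45 to 50.6 ± 2.39 CPM and from 38.9 ± 3.70 to 74.1 ± 7.47 CPM.

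Of the cell cycle inhibitors 5 of 18 fell and 1, Rbl1, rose (6 and 1 adjusted over the list alone). The list did not pass camera (adjusted p = 0.0654). It passed with the mouse as a block (0.0386), without the library labelled Axin2- of mouse 1 (0.0229) and without that labelled Axin2+ of mouse 1 (0.000791). It also passed with no filter on low counts (0.0458), with at least 1 CPM in 3 libraries (0.0472) and with the inferred filter of the authors' table (0.0488). Cdkn1c, an inhibitor of cyclin-dependent kinases, fell from 152 ± 9.72 to 58.1 ± 11.6 CPM. In the Notch pathway 5 of 25 rose and 3, Maml1, Maml3 and Numbl, fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.608). The receptor Notch1 rose from 127 ± 5.88 to 250.1 ± 21.8 CPM and the ligand Dll4 rose from 5.34 ± 0.343 to 18.5 ± 4.88 CPM. In the BMP and TGF-beta pathway 13 of 35 fell and 2, Bmpr1b and Id2, rose (14 and 2 adjusted over the list alone), with a median of -0.40. Its camera adjusted p was 0.00598, with adjusted p = 0.153 with an estimated correlation. The stromal fibroblast markers and the smooth muscle and pericyte markers fell further in the same libraries, with medians of -1.87 and -2.89. The co-receptor Tgfbr3 fell from 483 ± 85.7 to 182 ± 35.1 CPM and the BMP target Id3 fell from 64.6 ± 13.8 to 25.6 ± 4.64 CPM. Without the library labelled Axin2+ of mouse 2 the BMP and TGF-beta pathway genes that passed numbered 8.

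Muscle, stroma and mesenchyme genes fell in the libraries labelled Axin2+. Of the smooth muscle and pericyte markers 13 of 15 fell (13 adjusted over the list alone), with a median of -2.89. The camera adjusted p was 6.24e-16, with adjusted p = 0.185 with an estimated correlation. The smooth muscle actin Acta2 fell from 707 ± 294 to 23.7 ± 2.02 CPM and the actin-binding protein gene Cnn1 fell from 97.04 ± 43.3 to 2.67 ± 0.855 CPM. Of the stromal fibroblast markers 19 of 23 fell (22 adjusted over the list alone), with a median of -1.87. Its camera adjusted p was 3.47e-11, with adjusted p = 0.153 with an estimated correlation. Lum, a proteoglycan of the collagen matrix, fell from 429.9 ± 86.2 to 102 ± 27.1 CPM, and the collagen gene Col5a1 fell from 766 ± 338 to 134 ± 31.8 CPM. Of the epithelial-mesenchymal transition genes 12 of 18 fell and 1, Foxc2, rose (13 and 2 adjusted over the list alone), with a median of -1.28. Its camera adjusted p was 7.85e-05, with adjusted p = 0.158 with an estimated correlation. Snai2, a repressor of epithelial genes, fell from 16.03 ± 2.63 to 3.20 ± 0.430 CPM, and Zeb1, another, fell from 201 ± 23.5 to 57.4 ± 17.9 CPM. The libraries labelled Axin2- differed among themselves, with Myh11 at 2882, 822 and 2386 CPM in mice 1, 2 and 3. Of the stromal fibroblast markers 10 passed without the library labelled Axin2+ of mouse 2, and of the epithelial-mesenchymal transition genes 8 passed without the library labelled Axin2- of mouse 1.

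Markers of further cell types also moved with the fraction. Of the endothelial markers 10 of 18 rose (12 rose and 1 fell adjusted over the list alone), with a median of 1.62. The camera adjusted p was 0.00467, with adjusted p = 0.484 with an estimated correlation, and without mouse 2 the median was 0.94. The junction protein gene Esam rose from 8.16 ± 2.57 to 31.4 ± 9.56 CPM and the tight junction gene Cldn5 rose from 4.74 ± 1.61 to 17.8 ± 5.57 CPM. Of the immune cell markers 13 of 29 rose and 3, Cd3e, Nkg7 and Cd79a, fell (15 and 4 adjusted over the list alone). The list did not pass camera (adjusted p = 0.0654), but did without the library labelled Axin2- of mouse 3 (0.0447) and without that labelled Axin2+ of mouse 3 (0.000130). It also passed with upper quartile scaling (0.0454), with no filter on low counts (0.0349) and with at least 1 CPM in 3 libraries (0.0472). C1qc, a complement gene of macrophages, rose from 11.9 ± 8.33 to 176 ± 131 CPM, and did not pass without the library labelled Axin2- of mouse 1 (edgeR adjusted p = 0.0528). Its log2 fold change of 3.89 was 4.49 without the library labelled Axin2- of mouse 3 and 3.15 without that labelled Axin2+ of mouse 1. Cd3e, a subunit of the T cell receptor complex, fell from 6.21 ± 3.34 to 0.193 ± 0.221 CPM, a log2 fold change of -4.97 that was -6.51 without the library labelled Axin2+ of mouse 1. Of the mesothelial markers 6 of 10 rose and 1, the transcription factor Wt1, fell (8 and 1 adjusted over the list alone). The median of that list was 2.66, or 1.89 without the library labelled Axin2+ of mouse 1 (camera adjusted p = 0.00881 with all libraries, and adjusted p = 0.484 with an estimated correlation). Msln, the surface protein mesothelin, rose from 6.82 ± 3.91 to 53.6 ± 31.3 CPM, with a log2 fold change of 2.98 that was 3.58 without the library labelled Axin2- of mouse 1. Wt1 fell from 161 ± 22.9 to 75.1 ± 15.00 CPM. The counts of these cell types changed with single libraries: 3 endothelial markers passed without the library labelled Axin2+ of mouse 2, and 1 immune cell marker, a lower one, passed without the library labelled Axin2- of mouse 1.

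**Figure D3:**
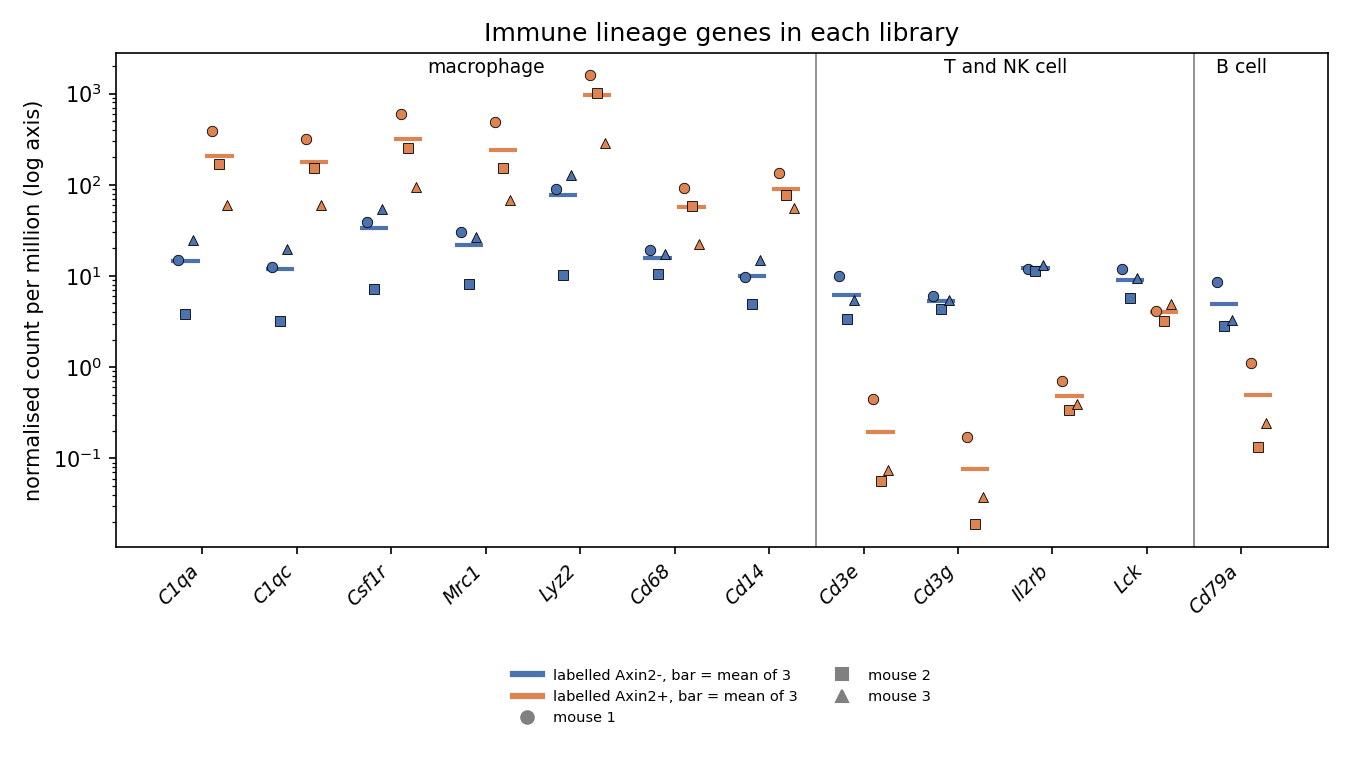
Normalised CPM on a log axis for 12 genes of macrophages, of T and NK cells and of B cells in each of the 6 libraries; marker shapes stand for the mouse and bars for the mean of 3 libraries, and the genes were chosen after their values were seen. C1qc lies between 3.23 and 19.9 CPM in the libraries labelled Axin2- and between 59.6 and 318 CPM in those labelled Axin2+, and Cd3e between 3.34 and 9.88 CPM and between 0.0566 and 0.449 CPM.

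Erythroid genes lay near the detection limit, and 2 of 3, Beta-s and Hba-a1, fell (2 adjusted over the list alone; camera adjusted p = 0.116). Hba-a1, an alpha-globin gene, was at 0 in the libraries labelled Axin2+, at least 22.1-fold lower against a floor of 3 counts per library. The median of the list was -6.11, or -4.46 with Hba-a1 at its bound, and without the library labelled Axin2- of mouse 1 neither gene passed (edgeR adjusted p = 0.0559 and 0.0563). Hba-a1 did not pass without the library labelled Axin2+ of mouse 2 either (0.0524). The 4 Beta-s reads in the libraries labelled Axin2+ all came from that of mouse 2, and without it Beta-s was at 0 there, at least 34.5-fold lower. Of the ovary and oviduct genes 1 of 5, the inhibin gene Inha, fell (2 adjusted over the list alone; camera adjusted p = 0.258). Inha kept its call only without the library labelled Axin2+ of mouse 3, and the other 5 removals gave adjusted p of 0.0510, 0.0768, 0.104, 0.0757 and 0.104.

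Of the dissociation and immediate early genes 11 of 31 fell in the libraries labelled Axin2+ and 20 did not pass (12 adjusted over the list alone). Their median was -0.97, or -1.87 without the library labelled Axin2+ of mouse 1 (camera adjusted p = 5.03e-05 with all libraries, and adjusted p = 0.484 with an estimated correlation). In that library 28 of the 31 genes exceeded both other libraries labelled Axin2+, with a median log2 ratio of 1.58 to their mean. Egr1, an immediate early transcription factor, fell from 5623 ± 1619 to 1006 ± 621 CPM, a log2 fold change of -2.48 that was -3.11 without that library. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, had log2 fold changes of -1.96 and -1.29. Of the antimicrobial and mucosal defence genes 8 of 20 rose (8 adjusted over the list alone), with a camera adjusted p of 0.000102 and adjusted p = 0.292 with an estimated correlation. Their median of 1.76 was 2.44 without the library labelled Axin2- of mouse 1 and 0.78 without that labelled Axin2+ of mouse 1. The general epithelial genes rose further in the same libraries, with a median of 3.69. The mucin Muc4 rose from 3.94 ± 0.663 to 34.6 ± 1.92 CPM, and Pigr, which carries antibodies across epithelium, rose from 2.72 ± 1.52 to 48.7 ± 5.11 CPM. Cell adhesion and basement membrane genes divided, with 8 of 27 rising and 13 falling (8 and 13 adjusted over the list alone; camera adjusted p = 0.962). The median of that list was -0.64 and its mean 0.076, which differ in sign. The integrin subunit gene Itgb4 rose from 21.1 ± 5.61 to 180.2 ± 34.4 CPM. Of the interferon response genes 5 of 30 rose and 1, Ifit2, fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.349). The RNA-sensing enzyme gene Oas2 rose from 1.60 ± 0.585 to 11.02 ± 6.24 CPM, while Ifit2 fell from 35.2 ± 6.57 to 17.5 ± 1.21 CPM. The dissociation and immediate early genes that passed numbered 3 without the library labelled Axin2- of mouse 3 and 26 without that labelled Axin2+ of mouse 1, and the interferon response genes 3 without that labelled Axin2- of mouse 1.

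Of the endometrial cancer driver genes 8 of 25 rose and 2, Pik3ca and Pik3r1, fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.228). The transcription factor Sox17 rose from 14.97 ± 6.89 to 249 ± 62.8 CPM and the mismatch repair gene Msh6 rose from 58.6 ± 2.51 to 84.4 ± 5.77 CPM. Of the glycolysis and hypoxia genes 7 of 25 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.349). The aldolase Aldoc rose from 1.16 ± 0.407 to 20.7 ± 4.73 CPM and the enolase Eno2 fell from 41.7 ± 6.27 to 13.2 ± 1.99 CPM. Of the cholesterol synthesis genes 5 of 23 rose (4 adjusted over the list alone; camera adjusted p = 0.228), among them Dhcr7 and Ebp, which did not pass without the library labelled Axin2+ of mouse 2 (edgeR adjusted p = 0.0511 and 0.0749). Of the oxidative phosphorylation genes 4 of 53 rose, Cox5a, Sdhd, Ndufa3 and Ndufa4 (2 adjusted over the list alone; camera adjusted p = 0.0816, or 0.00372 without the library labelled Axin2- of mouse 2). That list also passed in limma-voom (0.00333), with library-size scaling (0.0485) and with no filter on low counts (0.0385). Ndufa3 and Ndufa4 did not pass with the mouse as a block (adjusted p = 0.0785 and 0.0651) or without any single library, where the lowest adjusted p were 0.0552 and 0.0518. Of 64 cytosolic ribosomal protein genes edgeR called 0 (0 adjusted over the list alone), limma-voom called 0, DESeq2 called 6, and 6 had an unadjusted edgeR p under 0.05. Their median was -0.31 (camera adjusted p = 0.0164, and adjusted p = 0.762 with an estimated correlation). The list did not pass camera without the library labelled Axin2- of mouse 2 (adjusted p = 0.677), where its median was -0.00096, or that labelled Axin2+ of mouse 1 (adjusted p = 0.190, median -0.19). Of the nuclear and small structured non-coding RNAs 5 of 13 fell and 1, Snhg11, rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00547, and adjusted p = 0.484 with an estimated correlation). The list did not pass without the ribosomal and abundant structural RNA genes, some of them its own members (median -0.57, camera adjusted p = 0.143). Rmrp, the RNA of a ribonuclease that processes ribosomal RNA, fell from 1991 ± 443 to 386 ± 50.99 CPM, and Rn7sk fell from 5679.8 ± 686 to 2714 ± 144 CPM. Of the mitochondrially encoded protein genes 0 were tested. Fewer genes passed without the library labelled Axin2+ of mouse 2: 3 cancer driver genes, 5 glycolysis and hypoxia genes and 0 cholesterol synthesis genes. Of the oxidative phosphorylation genes 2 passed without the library labelled Axin2- of mouse 1 and 12 without that of mouse 2.

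Over all genes, 4618 changed between the fractions by edgeR's quasi-likelihood test at an adjusted p under 0.05, 2447 higher and 2171 lower in the libraries labelled Axin2+. The largest rises included, beside Cxcl15, Foxa2 and Ihh, those of Gpx2, a glutathione peroxidase of epithelia, which rose from 0.372 ± 0.216 to 13.3 ± 0.753 CPM, Ano2, a calcium-activated chloride channel, which rose from 0.948 ± 0.341 to 33.5 ± 5.82 CPM, and Gulo, an enzyme of vitamin C synthesis, which rose from 1.31 ± 0.512 to 40.7 ± 8.16 CPM. The largest falls included, beside Myh11 and Cnn1, those of Actg2, an actin of smooth muscle, which fell from 90.5 ± 44.02 to 1.51 ± 0.517 CPM, Lmod1, a muscle actin nucleator, which fell from 127 ± 73.4 to 3.01 ± 1.12 CPM, and Myocd, a cofactor that switches on smooth muscle genes, which fell from 34.8 ± 16.2 to 1.09 ± 0.438 CPM. Within each direction the smallest p belonged to the rises of Celsr2, Dsg2 and Gcnt1 and to the falls of Cntn1, Gem and Spock2. Celsr2, a cadherin of planar cell polarity, rose by 3.31 ± 0.13 (SE) on the log2 scale, and the desmosomal cadherin Dsg2 rose by 3.64 ± 0.16 (SE). In 7970 tested genes, 47.2%, the levels of the groups did not overlap, where chance gives 10%. Scaling by library size alone gave 3255 higher and 1573 lower, 67.4% higher in place of 52.99%, and shifted the median of all genes by 0.17 on the log2 scale. Without the library labelled Axin2+ of mouse 2 the count was 2544 (1491 higher and 1053 lower), and without the libraries labelled Axin2- of mice 1 or 3 the genes lower numbered 1272 or 1308. Of the 15469 genes in the authors' deposited table, 4664 had an adjusted p under 0.05, 2440 higher and 2224 lower, and Axin2 stood at -0.62 with an adjusted p of 0.0648. Of the genes called here, 4494 were also called in the authors' deposited table, 4494 with the same sign. Both rest on the same counts and the same kind of fit, so the shared signs are no separate evidence.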

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

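Choices fixed in advance made up these alternatives, except the fits without structural RNA genes and with the inferred filter of the authors' table, which were chosen after seeing the data. For named genes, 2522 of 2691 values kept their direction and their side of the threshold, 162 no longer passed, 5 newly passed, 3 of Pgr and 2 of Axin2, and 2, both of Esr1, changed sign. For lists, 594 of 649 values kept both, 25 no longer passed, 22 newly passed and 8 changed the direction of the test. With the mouse as a block (replicate block) 3954 genes changed, 2085 higher and 1869 lower in the libraries labelled Axin2+, of which 3659 were among the 4618, and Axin2 stood at -0.66. The block changed the calls of Pgr, Tie1, Ndufa3, Ndufa4 and the cell cycle inhibitors, and no other call of a named gene or list. A test against a fold of 1.5 gave 2321 genes, 1368 higher and 953 lower, fewer by construction. Axin2 passed in DESeq2 at -0.62, and the cause was not tested. With an estimated correlation 0 lists passed camera in place of 18. Fry, which asks another question, did not call the mesothelial markers (adjusted p = 0.0922), the dissociation and immediate early genes (0.0742) or the cytosolic ribosomal protein genes (0.392), which camera called, and called the cell cycle inhibitors (0.0467), erythroid genes (0.0467), ovary and oviduct genes (0.0262) and endometrial cancer driver genes (0.0114), which camera did not. Among called lists the median of the smooth muscle and pericyte markers became -3.65 and that of the uterine gland genes 3.72 with no filter on low counts, and that of the antimicrobial genes 1.16 with the block and 2.72 with at least 1 CPM in 3 libraries. The test direction of the cell adhesion list reversed with at least 1 CPM in 3 libraries (median -0.66) and in limma-voom (median -0.59), and the cause was not tested. Leaving out 1 library or 1 mouse gave 1711 to 4114 genes, 1018 to 2304 higher and 693 to 1911 lower, with fewer libraries by construction, and 18 to 19 lists. Without mouse 1, 2 or 3 the counts were 2522, 1711 and 2686. Over these removals the log2 fold change of Axin2 ranged from -0.82 to -0.37 and that of Esr1 from -0.65 to 0.074. The median of the ciliated cell list ranged from -0.75 to 0.13 and that of the cell adhesion list from -0.69 to -0.34. Of 30 lists with members that passed, 15 had over 1.5 times fewer without some library, with fewer libraries by construction. Depth limits the genes with 0 to 3 reads in a fraction, whose fitted folds, where they enter a median or a test, rest on those few reads.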

Other observations

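The lists and gene families of this part, and all its tests except the count of other splits of the libraries, were chosen after the result was seen. Immune lineages moved in opposite directions. Of 20 macrophage genes, 10 of them also in the fixed lists, 18 rose in the libraries labelled Axin2+ with a median log2 fold change of 3.45. That count changed with single libraries, with 5, 12 and 8 rising without the libraries labelled Axin2- of mice 1, 2 and 3, and 12, 9 and 19 without those labelled Axin2+. The median was 2.66 without the library labelled Axin2+ of mouse 1, which held the most of Lyz2, C1qa and Mrc1. Lyz2, the macrophage lysozyme, rose from 76.2 ± 60.5 to 962 ± 648 CPM, but did not pass without the libraries labelled Axin2- of mice 1 or 3 (adjusted p = 0.0905 and 0.0650) or those labelled Axin2+ of mice 1 or 2 (0.0572 and 0.0753). The receptor Trem2 rose from 0.796 ± 0.594 to 17.01 ± 8.89 CPM. Of 17 T and NK cell genes 13 fell, with a median of -4.34. Without the libraries labelled Axin2- of mice 1 or 3, 8 and 8 fell, with medians of -4.42 and -4.40. Il2rb, a subunit of the interleukin 2 receptor, fell from 12.2 ± 0.940 to 0.479 ± 0.199 CPM. The T and NK cell genes Xcl1 and Cd96 were at 0 in the libraries labelled Axin2+, at least 31.03-fold and 22.7-fold lower. Of 5 mast cell genes 5 fell, with a median of -5.62, or -5.14 with genes at 0 at their bound, and 1 fell without the library labelled Axin2- of mouse 1. Cpa3, a mast cell protease, had 232 reads in the libraries labelled Axin2- against 3, a ratio of 81.00 with a 95% counting interval of 27.4 to 396. Of 5 lymphatic endothelium genes 1, Prox1, rose, and it passed in 1 of the 6 removals of a library.

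Members of 10 gene families were counted, without a test of a family as a whole. Of 17 keratins 8 rose and 0 fell (median 2.86), and of 15 claudins 9 rose and 0 fell (median 2.77). Of 40 collagens 25 fell and 2 rose (median -1.65), and of 18 ADAMTS proteases 11 fell and 1 rose (median -1.71). Of 32 Hox genes 8 rose and 7 fell (median -0.82), and of 11 laminins 4 rose and 6 fell (median -0.64). Of 30 genes whose symbols start with Itga or Itgb, 7 rose and 9 fell (median -0.34). That set was picked by symbol and can hold genes that are not integrin subunits. Of 244 solute carriers 60 rose and 33 fell (median 0.16), of 17 aldehyde dehydrogenases 5 rose and 1 fell (median 0.070) and of 11 serpins of clade B 4 rose and 0 fell (median 0.49). The medians of all 10 families kept their sign under RLE, upper quartile and library-size scaling. Without 1 library the genes that passed went down to 17 collagens, 7 ADAMTS proteases, 9 Hox genes and 10 Itga and Itgb genes. They also went down to 60 solute carriers, 2 aldehyde dehydrogenases and 2 serpins of clade B. The median of the aldehyde dehydrogenases reached -0.053. Sult1c2, a sulfotransferase, and Vsig1, a junction protein, were at 0 in the libraries labelled Axin2-, and were at least 56.4-fold and 47.8-fold higher in those labelled Axin2+.

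Of the 10 splits of the 6 libraries into 3 and 3, which exchange libraries across mice, 1, the real one, gave as many genes as the 4618 called, and the highest of the others gave 0 in edgeR. The other splits had 81 to 711 genes with an unadjusted p under 0.05 and the real split 6855. Each other split puts libraries of both fractions in both groups, so the difference between fractions adds to the spread within groups. Their counts are therefore no measure of what chance gives. With 10 splits the share cannot go under 0.1.

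The Axin2 transcript was no higher in the libraries labelled Axin2+. Library scaling is argued against, since the highest log2 fold change over 4 scalings was -0.44 (SE 0.227), and so is an exchange of single libraries, since 0 libraries correlated better with the other fraction. An exchange of all labels stays open: the count table held 0 reporter transcripts, which could have decided it. Of the Wnt/beta-catenin targets 11 of 22 rose in the libraries labelled Axin2+ and 3 fell. The general epithelial genes rose there as well, so these targets do not decide it. Axin2 RNA of non-epithelial cells in the libraries labelled Axin2-, and a reporter protein that outlasts the transcript, stay open and were not tested.

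Foxa2, Cxcl15 and Ttr lay further below the libraries labelled Axin2+ than the general epithelial genes in the libraries labelled Axin2-. Dilution of one epithelial mixture by cells without these transcripts would lower all of them alike. These 3 of 10 gland genes exceeded the largest general epithelial fold, that of Msx2 at 4.42. Foxa2 did so by more than 2 SE, and Cxcl15 and Ttr, with 1 to 3 reads, by the low end of the counting interval, at 8.34 and 5.81. The SE is that of Foxa2 alone, with 4.42 taken as fixed although Msx2 had an SE of 0.49. The counting interval leaves out the spread between libraries. Such dilution alone would not give this excess, but the same genes define the pattern, so their count is no separate test. Counting error is argued against for Foxa2: at the lowest epithelial share 170.3 Foxa2 reads were expected, against 30 observed with an upper bound of 42.8. Mesothelial cells as the source of the general epithelial genes stay open. The 13 genes restricted to epithelium had a median of 3.79, below the 5.71 needed. All of them are also in the general list, where no fold exceeded 4.42, so this comparison could not have come out otherwise. A lower share of gland cells among the epithelial cells labelled Axin2- is a hypothesis from the same libraries and was not tested. Of the other gland genes Prom1 and Wfdc15b exceeded 4.42 by less than 2 SE, and the rest lay below it. These were Aldh1a1 at 3.38 and Sox17 at 4.05, and Lif at -0.35, Cited2 at -0.12 and Gpx3 at -2.21, which did not rise. Larger folds were not particular to gland genes, with Wif1 at 10.03, Serpinb11 at 7.85 and Bpifb5 at 7.46.

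Macrophage genes were higher and T and NK cell genes lower in the libraries labelled Axin2+. A smaller share of stroma and muscle would raise all other cell types alike, so it cannot alone give the median of -4.34 for T and NK cell genes. That median is part of the pattern itself and is no separate test. Whether such a share added to the rise of the macrophage genes was not tested. RNA or cells of macrophages carried through the sort, and a biological difference between the fractions in their immune cells, stay open and were not tested.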
